A study of Oryza sativa with 5 samples.

How the data were processed

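RNA was sequenced from wild-type and mutant rice material that the labels call grain cells, 3 wild-type and 2 mutant libraries, made with the SMARTER mRNA-Seq kit per the labels' protocols. The submitters' processing notes name Bowtie2, HISAT2 2.1.0, RSEM, StringTie and DESeq2 1.12.4 without saying what each was used for. The genome build those notes name is a mouse build, which cannot belong to rice locus identifiers, so the build of the coordinates printed here is not given in the sources used here. Whether counting used strand is not given in the sources used here either, so overlapping and antisense genes may share reads.

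The authors deposited whole-number counts per gene (42189 loci) and per transcript (52424 transcripts), the unit used for all main tests, and TPM values for the same features, used for an alternative and for gene lengths. FPKM values were not used. In these deposited counts, values of 2 and 4 were more frequent (4268 and 2926 cells) than 1 and 3 (1755 and 1647 cells), so counts are not all independent molecules. Counting intervals and the floor of 3 counts treat each count as independent, so the intervals may be too narrow even for counting error. Neither covers the spread between libraries. Counts divided by TPM gave the same relative length in all libraries within 1% for 100% of values in 11719 genes with a single transcript. Every row named a gene. The deposited annotation gave a name for 11681 loci, a description for 25292 and a KEGG pathway for 5312, with names of Arabidopsis relatives. A further 1 column, of FPKM values for transcripts, has a name like those of the mutant columns with another number. It matched no sample given here and was not used.

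Columns were matched to libraries by genotype and number. Pairs of libraries were compared by a chi-square of their counts: the lowest value per degree of freedom was 24.3, so no pair agreed within sampling noise and none was counted as 1 sample. Total counts were 32564678 to 40618376 per library, and 3 counts correspond to 0.0768 to 0.0968 CPM.

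The main test was edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM normalization (factors 0.952 to 1.08), robust quasi-likelihood fit, two-sided test and Benjamini-Hochberg adjustment with a threshold of 0.05, over all 5 libraries with no covariate. CPM values are normalised read counts on TMM-scaled library sizes. Standard errors are the fold change divided by the square root of the F statistic. The same test was run on transcripts. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Fry tests whether a list's genes move one way on balance, not against other genes. There were 30 lists fixed before the data were examined, of which 28 had at least 5 tested members: seed storage proteins, seed allergens and inhibitors, starch synthesis, starch degradation, sucrose, LEA proteins, oil body proteins, small and larger heat shock proteins, endoplasmic reticulum chaperones, photosynthesis, cytosolic ribosomal proteins, histones, cyclins and their kinases, cell wall expansion, auxin, gibberellin, abscisic acid, cytokinin, brassinosteroid, ethylene, jasmonate, antioxidant enzymes, pathogenesis-related proteins, NB-ARC genes, small RNA machinery, transposons, proteasome, respiratory chain and grain size genes. Lists were made from the wording of the deposited descriptions and from locus identifiers. Of the 28, camera called 4 up and 4 down, 0 held with an estimated correlation (where 1, histones, had an unadjusted p under 0.05, of 0.0330), and fry called 14. Median, mean and test differed in sign for small heat shock proteins, starch synthesis, gibberellin, cytokinin, transposon and respiratory chain lists, none of them called by camera. KEGG pathways with at least 10 tested members (124) and 5 lists of floral genes were added after the data were examined.

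Genes named in the text follow a rule fixed before the data were examined: among genes past the threshold with a mean of at least 5 CPM and no overlap between genotypes, the 10 largest rises and 10 largest falls with a name or description and at most 2 without per direction, and from each list up to 4 members with the smallest adjusted p, or up to 2 most abundant members where none passed. Genes outside the rule are said to be chosen later. Bounds of the form at least N-fold set the floor of 3 counts per library in place of 0 counts, and ratios to 1 to 3 counts carry exact Poisson intervals at 95%. The share of storage protein counts was compared with an exact permutation test, with Clopper-Pearson intervals per library.

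The edgeR step was tested on simulated counts drawn from the real means and library sizes. For genes (25915 tested), it recovered 40% of 100 genes changed 2-fold and 96% of 100 changed 4-fold, with 4 false calls among 140. For transcripts (34991 tested), it recovered 4% at 2-fold and 45% at 4-fold. A far smaller share was changed than was called in the data, 29.4% of genes and 12.9% of transcripts. The adjusted threshold was therefore stricter in the simulation, and its recovery does not measure recovery in the data. The simulated variation followed the trend with mean expression only. In camera, 1 list raised 2-fold among 17 was recovered with 0 other lists called. The simulated genes were drawn independently, so false calls from genes that move together were not tested.

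Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, median-of-ratios size factors, no filter, a filter of at least 10 CPM in at least 2 libraries, log2(TPM + 1) with limma-trend, a fold minimum of 2, each library left out and a replicate block. Where 1 mutant library is left, it is assumed to vary like the wild type. Added later were library totals without normalization factors, a refit without photosynthesis genes and leaving out genes within 500 kb of genes detected in 1 genotype only. Figures were drawn with matplotlib 3.10.9.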

Results

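Gene expression was measured by RNA sequencing in rice, Oryza sativa, of the cultivar Nipponbare, the japonica line on which much rice genomics rests, and in a mutant of it. The labels call the material grain cells of the mature period and do not name the mutated gene, so no targeted gene could be checked against the labels. There were 3 wild-type libraries and 2 mutant libraries. Total counts were 32564678, 40618376 and 39052071 in wild-type replicates 1, 2 and 3, and 36310010 and 36721676 in mutant replicates 2 and 3. Between 28338 and 29094 genes had at least 1 count per library. The labels do not say whether the libraries came from separate plants, so p-values measure the spread between these libraries. Across genes, the correlation of log2 CPM was 0.960 to 0.984 between libraries of the same genotype and 0.847 to 0.906 between genotypes. Wild-type replicate 1 stood somewhat apart from the other wild-type libraries, with correlations of 0.960 to each of them, against 0.984 between replicates 2 and 3. The first principal component held 73.9% of the variance and separated the genotypes, and the second, with 13.4%, set wild-type replicate 1 apart.

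The comparison implied by the design is mutant against wild type. Genes with no counts in wild type and clear expression in the mutant included several receptor kinases and receptor-like proteins, which sit at the cell surface and sense pathogens or wall damage. Normalised read counts (CPM) are given as means ± SD with n = 3 for wild type and n = 2 for the mutant throughout. Gene names are those of the deposited annotation, which follow Arabidopsis relatives. LOC_Os01g05530, described as a Brix domain protein of ribosomal RNA processing (chromosome 1, 2632554 to 2638081), had no counts in wild type and 45.8 ± 5.96 CPM in the mutant, at least 546-fold higher. The bound sets 3 counts per library in place of 0 and does not cover the spread between libraries. Counting intervals given below treat each count as independent and may be too narrow. AtRLP23 (LOC_Os01g06900, chromosome 1, 3272839 to 3276416) was at least 250-fold higher, with 21.0 ± 3.77 CPM in the mutant. The wall-associated kinases WAK3 (LOC_Os04g29770) and WAK2 (LOC_Os04g30160) were at least 232-fold and at least 224-fold higher. The receptor-like kinase RLK1 (LOC_Os04g12600) was at least 167-fold higher, and the aldehyde oxidase AAO2 (LOC_Os10g04860) at least 243-fold. CRK12 (LOC_Os04g30030), a cysteine-rich receptor-like kinase, had 3 counts in all wild-type libraries together and 45.3 ± 6.94 CPM in the mutant, a ratio of 1771 with a 95% counting interval of 606 to 8588. ATPR1 (LOC_Os01g28450), whose relatives are markers of defence, rose from 0.0693 ± 0.0799 to 90.9 ± 29.6 CPM. BGAL7 (LOC_Os10g19960), a beta-galactosidase, rose from 0.104 ± 0.181 to 59.4 ± 44.2 CPM. ATPRP2 (LOC_Os10g05750) rose from 0.276 ± 0.215 to 19.2 ± 22.6 CPM, and its call was lost in limma-voom (adjusted p = 0.129), without wild-type replicate 2 (0.0574 in edgeR) and without wild-type replicate 3 (0.0674).

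Among genes with a name or description, the largest fall to no counts in the mutant was that of GASA3 (LOC_Os05g35690, chromosome 5, 21198101 to 21198992), a member of the gibberellin-responsive GAST1 family. It fell from 51.2 ± 19.9 CPM in wild type to no counts in the mutant, at least 658-fold lower. The subtilisin-like protease AIR3 (LOC_Os06g40700) was at least 452-fold lower, and the lipase MPL1 (LOC_Os06g42860) at least 276-fold lower. The BTB and MATH domain genes ATBPM4 (LOC_Os11g41360) and ATBPM3 (LOC_Os07g20130) were at least 169-fold and at least 144-fold lower. A GDSL lipase, LOC_Os04g55660, was at least 169-fold lower, the esterase LOC_Os10g05088 at least 142-fold and the galactosyltransferase LOC_Os01g65590 at least 130-fold. The glycosyl hydrolase LOC_Os11g19160 had 100.1 ± 40.0 CPM in wild type and 2 counts in the mutant libraries together, a ratio of 3801 with a 95% counting interval of 1052 to 31387. LOC_Os04g33930, a lipid-transfer protein, fell from 87.4 ± 40.9 to 0.105 ± 0.149 CPM. Among loci with no name or description, LOC_Os10g16440 and LOC_Os10g20480 were at least 600-fold and at least 331-fold higher, and LOC_Os01g41170 and LOC_Os02g32080 at least 3783-fold and at least 1338-fold lower.

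In all, 7695 of 26132 tested genes differed at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3801 higher and 3894 lower in the mutant. At least 2-fold changes made up 1932 of the higher and 2615 of the lower genes. The biological coefficient of variation was 24.5%, and the smallest adjusted p was 0.00152. In each of the 7695 genes the CPM of the 3 wild-type and 2 mutant libraries did not overlap, which held for 60.8% of all tested genes against 20% by chance. The calls select for such separation, and genes of the same libraries are not independent, so these shares are no separate support. The count of called genes fell to 4550 and 4004 without wild-type replicates 2 and 3. Without wild-type replicate 1, in a fit of the same size, it was 7746. With library totals as the only scaling, 61.7% of the calls were higher in the mutant, and with log2(TPM + 1) values 60.6%, against 49.4% here.

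A set of genes had counts in the libraries of 1 genotype only, defined after the data were examined as at most 3 counts in each library of a genotype and a mean of at least 100 in the other. There were 27 such genes in the mutant and 26 in the wild type. Of the 27, 15 lay on chromosome 4, 5 on chromosome 10 and 4 on chromosome 1, while chromosomes 4 and 10 held 8.84% and 5.32% of the tested genes. Runs of neighbouring genes were among them, such as WAK3, WAK4 (LOC_Os04g29790), LOC_Os04g29810, CRK12 and WAK2 between 17739613 and 18005396 on chromosome 4. Another pair was AtRLP19 (LOC_Os01g06890) and AtRLP23 on chromosome 1. The wall-associated kinases here are neighbouring members of 1 family, and their sequence similarity was not measured here.

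**Figure D1:**
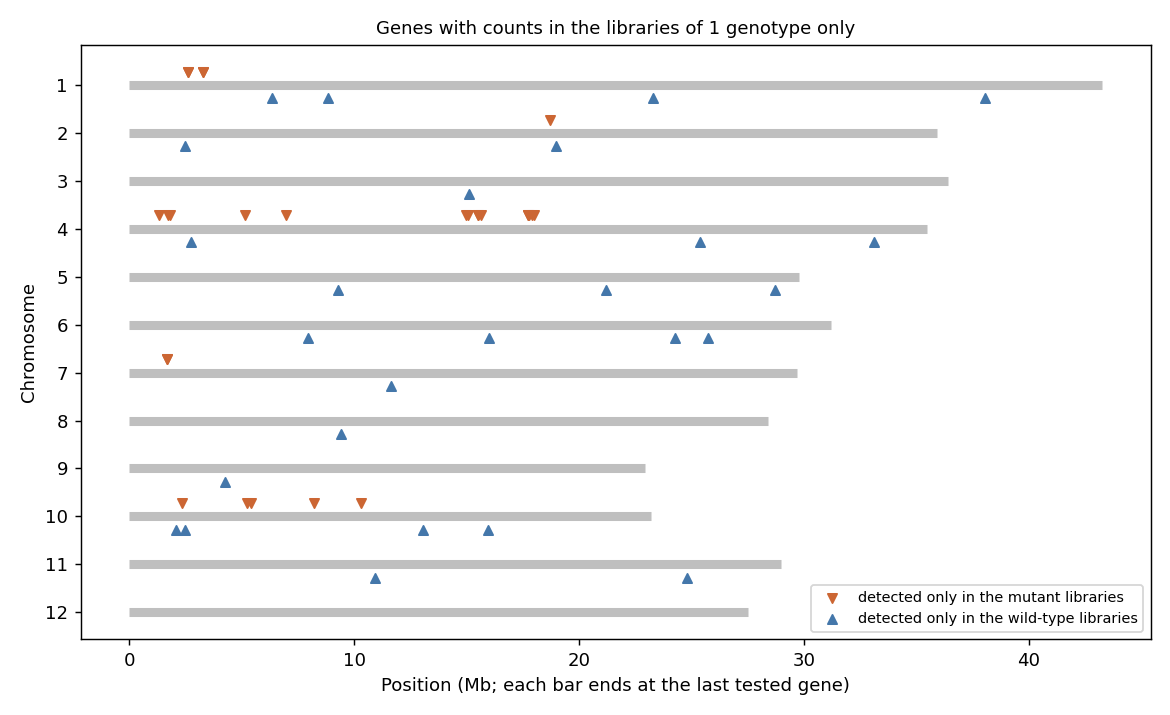
Positions of the genes with counts in the libraries of 1 genotype only, along rice chromosomes 1 to 12 as grey bars in Mb. Triangles above a bar mark the 27 genes detected only in the mutant libraries, of which 15 are on chromosome 4, and triangles below a bar mark the 26 detected only in the wild-type libraries.

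Starch breakdown genes were lower in the mutant. Of 19 tested members of the starch degradation list, 11 fell and 1 rose, with the same numbers when adjusted over the list alone. The beta-amylases, which release maltose from starch, led the change: BAM1 (LOC_Os10g32810) fell from 2514 ± 246 to 476 ± 10.8 CPM, a log2 fold change of -2.40 (SE 0.16). A further locus annotated BAM1, LOC_Os03g04770, fell from 2281 ± 279 to 760 ± 19.2 CPM, and BAM2 (LOC_Os09g39570) from 147 ± 10.7 to 41.5 ± 3.80 CPM. AT-BETA-AMY (LOC_Os07g35880) fell from 3.28 ± 0.949 to 0.0783 ± 0.0383 CPM. The list's median log2 fold change was -0.74, with an adjusted p of 0.00392 in camera and an adjusted p of 0.413 with an estimated correlation, and it was -1.15 without mutant replicate 2. Also lower in these libraries were 3 of 3 stamen and lodicule identity genes (median -2.04) and 9 of 17 anther and tapetum genes (median -1.38). Both lists were chosen after the data were examined. Of 22 starch synthesis genes, 3 rose and 3 fell, and the same when adjusted over the list alone, with a median of -0.21 and a mean of 0.04. The members that moved were not all biosynthetic: isoamylase ATISA3 (LOC_Os09g29404), whose relatives debranch starch during breakdown, fell from 157 ± 6.06 to 48.3 ± 13.7 CPM. The branching enzyme SBE2.2 (LOC_Os02g32660) fell from 169 ± 11.7 to 51.1 ± 25.1 CPM. LOC_Os03g55090, of the starch phosphorylase family, rose from 14.6 ± 1.75 to 57.9 ± 25.4 CPM. CYT1 (LOC_Os01g62840), described as of the glucose-1-phosphate adenylyltransferase family, rose from 117 ± 13.1 to 194 ± 7.06 CPM. The CYT1 call was lost without wild-type replicate 2 (adjusted p = 0.0520 in edgeR) and without wild-type replicate 3 (0.0569). In the sucrose list, 3 of 29 genes rose and 6 fell, with 3 and 7 adjusted over the list alone. ATSUS4 (LOC_Os03g28330), a sucrose synthase, rose from 162 ± 16.4 to 467 ± 24.3 CPM. The cell wall invertase AtcwINV2 (LOC_Os04g33720), which splits sucrose outside the cell, fell from 44.5 ± 27.0 to 0.0512 ± 0.0725 CPM, and the sucrose transporter ATSUC3 (LOC_Os10g26470) from 119 ± 27.2 to 18.5 ± 10.2 CPM.

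**Figure D2:**
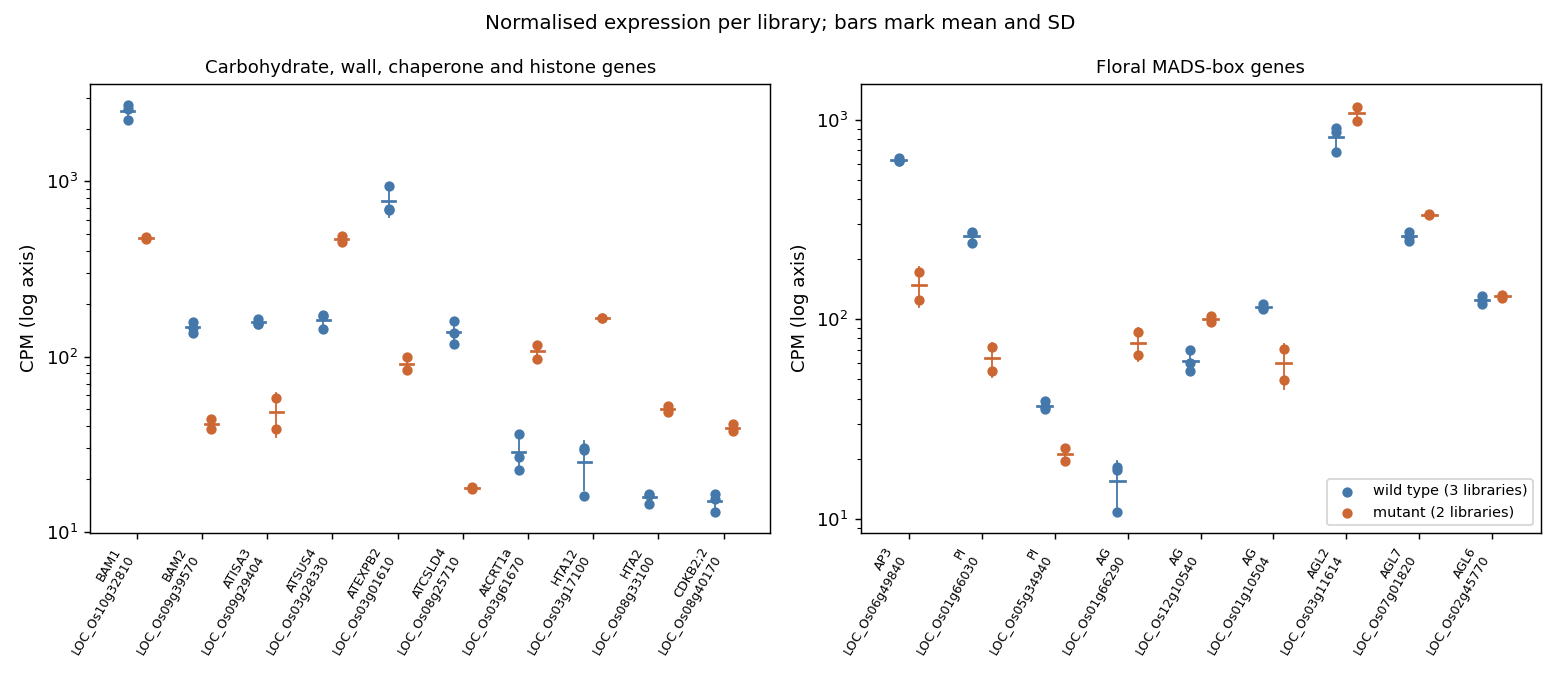
Normalised expression in CPM on a log axis, each point a library, with the mean and SD of the 3 wild-type and 2 mutant libraries. On the left BAM1 falls from 2514 to 476 CPM and the histone gene HTA12 rises from 25.1 to 166 CPM. On the right, among floral MADS-box genes chosen after the data were examined, AP3 falls from 628 to 149 CPM while AGL6 (LOC_Os02g45770) lies at 125 and 130 CPM.

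Lists of lipid storage and desiccation genes did not pass in camera, though single members fell. Of 7 oil body genes, which coat lipid droplets in seeds and pollen, 5 fell and 1 rose, also when adjusted over the list alone. In the same libraries 3 of 3 stamen and lodicule identity genes and 9 of 17 anther and tapetum genes were lower. The caleosins LOC_Os06g14350 and LOC_Os02g50140 fell from 29.5 ± 6.11 to 2.14 ± 0.638 CPM and from 23.5 ± 4.36 to 6.07 ± 0.688 CPM, and the oleosin LOC_Os05g50110 from 15.9 ± 3.74 to 1.57 ± 1.03 CPM. The oil body list's median was -1.94, with an adjusted p of 0.00780 in fry and 0.0528 in camera. In camera it passed without wild-type replicate 1 (adjusted p = 0.0379) and without wild-type replicate 2 (0.0402), but not without wild-type replicate 3 (0.0962). Its median was -1.51 without mutant replicate 2 and -1.93 without mutant replicate 3. Of 20 LEA protein and dehydrin genes, 3 fell and none rose, also adjusted over the list alone (camera adjusted p = 0.459). The dehydrin LOC_Os03g45280 fell from 540 ± 64.0 to 195 ± 24.2 CPM. Of 3 seed allergen and inhibitor genes, 1 fell, also adjusted over the list alone. This was LOC_Os03g29350, and its call was lost without mutant replicate 3 (adjusted p = 0.0834 in edgeR). Of 19 genes that set grain size in rice, 2 rose and 5 fell, also adjusted over the list alone. LOC_Os07g41200 fell from 97.9 ± 7.47 to 38.4 ± 2.17 CPM. BSL3 (LOC_Os03g44500), a phosphatase of brassinosteroid signalling, fell from 121 ± 14.9 to 66.6 ± 2.70 CPM, a call lost without mutant replicate 3 (adjusted p = 0.0580 in edgeR).

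Storage protein transcripts were almost absent from both genotypes, although the labels call the material mature grain. Floral genes were abundant instead, with AP3 (LOC_Os06g49840) at 628 ± 12.6 CPM and AGL2 (LOC_Os03g11614) at 820 ± 117 CPM in wild type, and no reference tissue was compared here, so changes in seed gene lists are given without reading them as changes of grain filling. The 13 storage protein genes held 3.78 ± 0.914 CPM of the library totals in wild type and 3.88 ± 0.937 CPM in the mutant. The difference was smaller than the spread between libraries (exact permutation test, two-sided, p = 0.8, where the 10 arrangements of 3 against 2 libraries allow no p under 0.2). Per library the 13 genes together had 112 to 167 counts. The share in wild-type replicate 1, 0.000451%, had a 95% Clopper-Pearson interval of 0.000381% to 0.000531%. Only 4 of the genes had enough counts to be tested and 0 passed in edgeR, also adjusted over the list alone, with 1 at an unadjusted p under 0.05 and 0 past the threshold in DESeq2 and limma-voom. The most abundant, the cupins ATCRA1 at LOC_Os10g26060 and LOC_Os01g55690, had 1.78 ± 0.406 and 1.26 ± 0.495 CPM in wild type and 2.19 ± 0.667 and 1.003 ± 0.332 in the mutant. By contrast, the 107 photosynthesis genes held 4.09% ± 0.442 of wild-type counts and 3.04% ± 0.0926 of mutant counts (exact permutation test, two-sided, p = 0.2, the smallest this design allows).

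Photosynthesis genes were lower in the mutant as a group. Of 92 tested, 30 fell and 6 rose, with 37 and 7 adjusted over the list alone. The median log2 fold change was -0.42 (camera adjusted p = 0.00478; adjusted p = 0.413 with an estimated correlation). LOC_Os08g39430, a PsbP-like protein of photosystem II, fell from 21.1 ± 3.16 to 6.92 ± 1.08 CPM. Members that rose included the early light-induced proteins ELIP2 (LOC_Os01g14410), from 199 ± 22.8 to 518 ± 116 CPM, and ELIP (LOC_Os07g08160), from 82.1 ± 7.63 to 208 ± 56.0 CPM, which protect chloroplasts under light stress. RBCS1A at LOC_Os02g05830 rose from 7.68 ± 0.909 to 23.3 ± 5.55 CPM. The camera call was lost without mutant replicate 2 (adjusted p = 0.0796). The stamen and anther markers fell in the same libraries, with medians of -2.04 and -1.38.

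Ribosomal protein, calreticulin and proteasome genes were higher in the mutant, in libraries in which the stamen and anther markers were lower (medians of -2.04 and -1.38). Of 9 tested genes of the cytosolic ribosomal protein list, which the deposited text describes as 60S acidic or 40S SA proteins, 8 rose and none fell, also adjusted over the list alone. LOC_Os01g09510 rose from 50.1 ± 6.59 to 119 ± 7.81 CPM and LOC_Os08g02340 from 162 ± 6.57 to 291 ± 4.76 CPM. The median was 0.61 (camera adjusted p = 0.000499; adjusted p = 0.413 with an estimated correlation). Of 6 genes of the endoplasmic reticulum chaperone list, 4 rose and none fell, with 5 and 0 adjusted over the list alone. The 4 were calreticulins, calcium-binding chaperones of glycoprotein folding, such as AtCRT1a (LOC_Os03g61670), from 28.5 ± 7.11 to 107 ± 14.4 CPM, and AtCRT3 (LOC_Os05g43170), from 45.1 ± 13.8 to 176 ± 47.6 CPM. The median was 1.02 (camera adjusted p = 0.00849; adjusted p = 0.413 with an estimated correlation), and the camera call was lost without mutant replicate 2 (adjusted p = 0.0551). Of 41 proteasome genes, 15 rose and none fell, with 19 and 0 adjusted over the list alone. PAC1 rose at LOC_Os06g07878, from 6.77 ± 0.627 to 16.7 ± 0.619 CPM, and at LOC_Os06g07978, from 6.47 ± 0.749 to 16.9 ± 0.789 CPM, a pair whose reads were not tested for sharing. The median was 0.33 (camera adjusted p = 4.7e-06; adjusted p = 0.413 with an estimated correlation).

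Histone genes were also higher. Of 13 histone genes, 10 rose and none fell, also adjusted over the list alone. HTA12 (LOC_Os03g17100), an H2A gene, rose from 25.1 ± 7.83 to 166 ± 0.527 CPM, HTA2 (LOC_Os08g33100) from 15.7 ± 1.14 to 50.1 ± 2.96 CPM, and HTA11 (LOC_Os10g28230) from 13.7 ± 2.62 to 58.8 ± 1.16 CPM. The median was 0.75 (camera adjusted p = 0.000172; adjusted p = 0.413 with an estimated correlation). Stamen and anther markers were lower in the same libraries (3 of 3 and 9 of 17). The tested members of the cyclin and cyclin-dependent kinase list were kinases, their activating factors and their inhibitors, with no cyclin. Of these 14, 3 rose and none fell, also adjusted over the list alone. CDKB2;2 (LOC_Os08g40170), a kinase active around mitosis, rose from 14.9 ± 1.80 to 39.3 ± 2.69 CPM. CDKB1;2 (LOC_Os01g67160) rose from 14.2 ± 1.86 to 26.5 ± 2.63 CPM, a call lost without wild-type replicate 3 (adjusted p = 0.0561 in edgeR) and mutant replicate 3 (0.0625). The third was ICK5 (LOC_Os11g40030), an inhibitor of these kinases, from 0.259 ± 0.113 to 1.57 ± 0.465 CPM, a call lost without mutant replicate 2 (0.0849). The list did not pass in camera (adjusted p = 0.145).

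Cell wall expansion genes went both ways, with more lower. Of 99 tested, 34 fell and 17 rose, with 39 and 17 adjusted over the list alone, and a median of -0.28 (camera adjusted p = 0.0225; adjusted p = 0.562 with an estimated correlation). Without wild-type replicate 1 the camera adjusted p was 0.0536. Stamen and lodicule identity genes (3 of 3) and anther and tapetum genes (9 of 17) were lower in the same libraries. The cellulose synthase-like genes ATCSLD4 (LOC_Os08g25710) and ATCSLD1 (LOC_Os06g22980) fell from 138 ± 21.3 to 17.7 ± 0.272 CPM and from 69.4 ± 11.8 to 9.63 ± 0.573 CPM. The expansin ATEXPB2 fell at LOC_Os03g01610 from 771 ± 142 to 91.2 ± 10.7 CPM and at LOC_Os03g01650 from 745 ± 135 to 88.9 ± 10.96 CPM, neighbours whose reads were not tested for sharing.

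**Figure D3:**
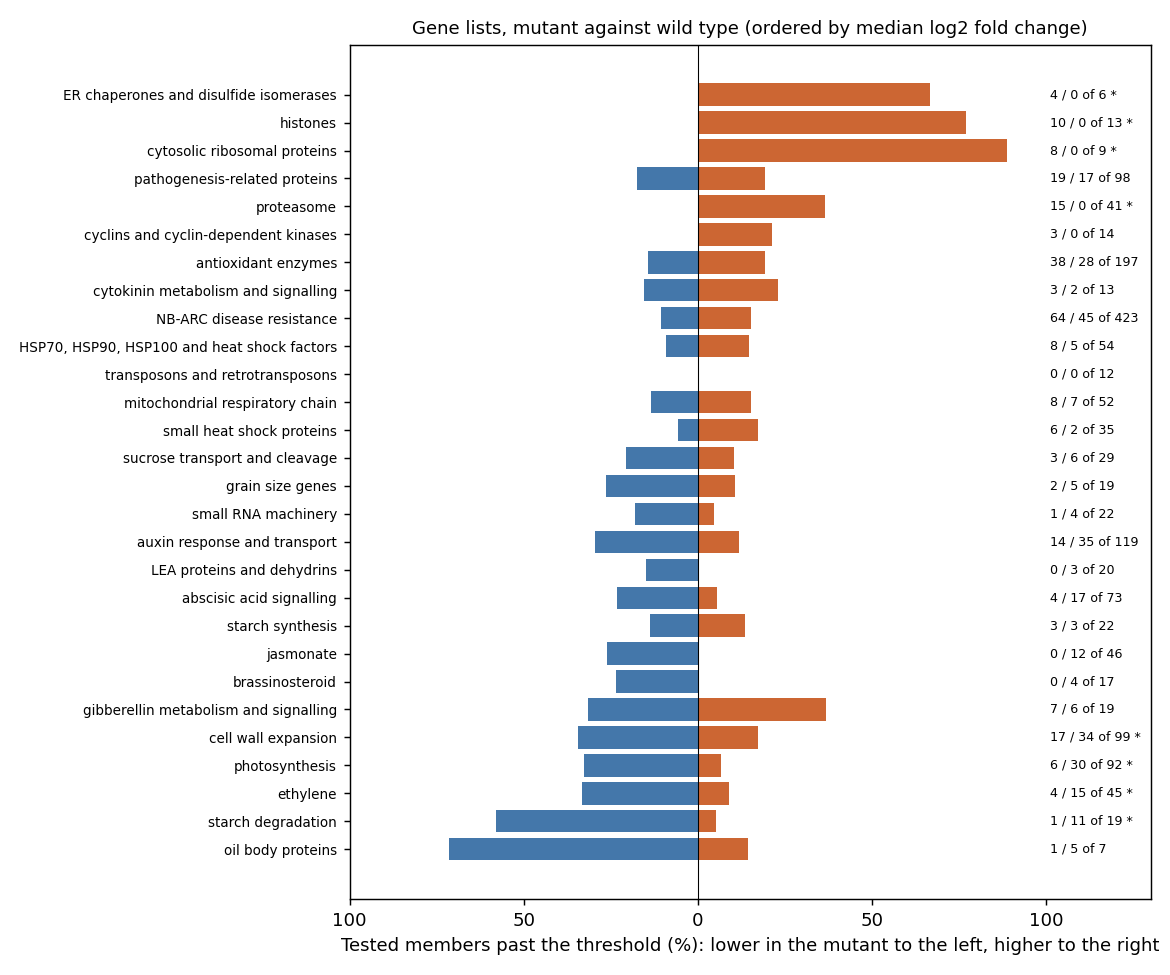
Percentage of tested members of each gene list that were lower (left, blue) or higher (right, orange) in the mutant at an adjusted p under 0.05 in edgeR, for the 28 lists with at least 5 tested members. The numbers on the right give higher / lower of tested, a star marks a list past the threshold in camera, and the ribosomal list shows 8 of 9 members higher while the starch degradation list shows 11 of 19 lower.

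In the lists of ethylene, jasmonate, auxin and abscisic acid genes more members fell than rose. Of 45 ethylene genes, 15 fell and 4 rose, also adjusted over the list alone. ATEBP (LOC_Os05g29810) fell from 55.7 ± 8.49 to 6.61 ± 1.01 CPM, ATERF15 (LOC_Os03g64260) from 14.9 ± 4.98 to 0.898 ± 0.256 CPM and the receptor EIN4 (LOC_Os04g08740) from 84.7 ± 4.45 to 37.0 ± 3.25 CPM. The median was -0.44 (camera adjusted p = 0.0225; adjusted p = 0.413 with an estimated correlation), and the camera call was lost without mutant replicate 2 (adjusted p = 0.104). The stamen and anther lists, with medians of -2.04 and -1.38, were lower in the same libraries. Of 46 jasmonate genes, 12 fell and none rose, with 11 and 0 adjusted over the list alone. JAZ1 (LOC_Os03g27900), a repressor that jasmonate itself induces, fell from 51.7 ± 12.4 to 9.94 ± 4.60 CPM, and LOX5 (LOC_Os03g49380), a lipoxygenase, from 167 ± 17.9 to 56.4 ± 15.5 CPM. The jasmonate list missed the threshold (camera adjusted p = 0.0625). Its median of -0.221 depended on the mutant library: it was -0.0375 without mutant replicate 2 and -0.619 without mutant replicate 3. Of 119 auxin genes, 35 fell and 14 rose, with 36 and 16 adjusted over the list alone. The GH3 genes FIN219 (LOC_Os01g12160) and DFL1 (LOC_Os05g42150), of the family that conjugates auxin or jasmonate to amino acids, fell from 32.6 ± 1.11 to 4.77 ± 0.899 CPM and from 66.8 ± 9.58 to 15.9 ± 3.09 CPM. Of 73 abscisic acid genes, 17 fell and 4 rose, also adjusted over the list alone. The type 2C protein phosphatase LOC_Os03g04430 fell from 401 ± 9.91 to 153 ± 9.95 CPM. The auxin and abscisic acid lists did not pass in camera (adjusted p = 0.168 and 0.145), and with library totals as the only scaling the auxin median was 0.01 rather than -0.12, while it was -0.23 without mutant replicate 3.

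Of 17 brassinosteroid genes, 4 fell and none rose, also adjusted over the list alone, among them BRH1 (LOC_Os04g49000), from 64.8 ± 14.7 to 15.0 ± 2.87 CPM. Of 19 gibberellin genes, 7 rose and 6 fell, also adjusted over the list alone. ATGA3OX1 (LOC_Os05g08540), which makes active gibberellin, fell from 73.1 ± 13.7 to 6.997 ± 4.20 CPM, and ATGA2OX1 (LOC_Os05g48700), which inactivates it, from 3.80 ± 0.826 to 0.285 ± 0.105 CPM. Of 13 cytokinin genes, 3 rose and 2 fell, also adjusted over the list alone. The cytokinin oxidase ATCKX5 (LOC_Os01g56810), which degrades the hormone, fell from 163 ± 29.1 to 35.1 ± 5.12 CPM. None of these lists passed in camera (adjusted p = 0.168, 0.790 and 0.790). Fry called the brassinosteroid list lower (adjusted p = 0.00821). Of other lists not past in camera, fry called auxin (0.00780), abscisic acid (0.0242) and sucrose (0.0460) lower. It called the list of cyclins and their kinases higher (0.0216).

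Defence and stress lists held changes in both directions, and none passed in camera. Of 98 pathogenesis-related genes, 19 rose and 17 fell, with 20 and 18 adjusted over the list alone (camera adjusted p = 0.553). Beside ATPR1, the thaumatin LOC_Os06g47600 rose from 19.7 ± 4.11 to 119 ± 11.3 CPM, and the chitinase ATHCHIB (LOC_Os05g33140) fell from 96.4 ± 9.17 to 7.44 ± 0.388 CPM. Of 423 NB-ARC resistance genes, 64 rose and 45 fell, with 59 and 38 adjusted over the list alone (camera adjusted p = 0.662). LOC_Os04g25900 had no counts in wild type and was at least 87.4-fold higher. EDR2 (LOC_Os02g01270), which carries resistance in its name and is not an NB-ARC protein, fell from 85.0 ± 9.62 to 9.80 ± 2.58 CPM. Of 197 antioxidant enzyme genes, 38 rose and 28 fell, with 39 and 28 adjusted over the list alone (camera adjusted p = 0.434). The peroxidase LOC_Os06g27850 fell from 195 ± 9.60 to 30.8 ± 9.89 CPM. Of 35 small heat shock genes, 6 rose and 2 fell, with 5 and 2 adjusted over the list alone. Of 54 larger heat shock genes and factors, 8 rose and 5 fell, with 7 and 5 adjusted over the list alone, and AT-HSFB2A (LOC_Os04g48030), a heat shock factor, rose from 17.3 ± 3.40 to 46.6 ± 2.25 CPM. Of 52 respiratory chain genes, 8 rose and 7 fell, also adjusted over the list alone.

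The series title names small RNA sequencing too, which was not analysed here. Of 22 small RNA machinery genes, 1 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.459). AGO2 (LOC_Os04g52540), an Argonaute, had 133 ± 2.16 CPM in wild type and 88.4 ± 11.5 in the mutant, and its call was lost without wild-type replicate 2 (adjusted p = 0.0614 in edgeR), wild-type replicate 3 (0.0676) or mutant replicate 2 (0.0864). An RNA-dependent RNA polymerase, LOC_Os01g10130, rose from 1.06 ± 0.1405 to 3.56 ± 1.124 CPM, a call lost without mutant replicate 2 (0.0586). Of 12 tested transposon genes, 0 passed in edgeR over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05, 1 past the threshold in DESeq2 and 0 in limma-voom. The most abundant, LOC_Os02g46920, had 54.0 ± 17.0 CPM in wild type and 37.6 ± 12.4 in the mutant.

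At the level of transcripts, 4542 of 35116 tested isoforms differed in edgeR's quasi-likelihood test, 2086 higher and 2456 lower, with a biological coefficient of variation of 46.6%. DESeq2 called 9640, and more were higher than lower with library totals as the only scaling (2819 and 2145) and with log2(TPM + 1) values (3482 and 2576). Of the genes with a called transcript, 4166 were also called as genes and 195 were not. In 33 of 5757 genes with at least 2 tested transcripts, called isoforms moved in opposite directions. Ranked by the lower of 2 levels, that of the rising isoform in the mutant and that of the falling isoform in wild type, the first 4, chosen after the data were examined, were ATRAN3, LTP3, PMSR4 and AGO1. For AGO1 (LOC_Os04g47870), the Argonaute that carries microRNAs in Arabidopsis, LOC_Os04g47870.2 fell from 201 ± 38.9 to 48.4 ± 15.2 CPM while LOC_Os04g47870.1 rose from 7.28 ± 1.0008 to 107 ± 15.1 CPM. For LTP3, a lipid transfer protein, LOC_Os12g02340.1 fell from 1031 ± 31.6 to 127 ± 25.6 CPM and LOC_Os12g02340.2 rose from 1.38 ± 0.348 to 126 ± 23.7 CPM. For PMSR4, LOC_Os10g41400.2 fell from 122 ± 20.1 to 1.72 ± 0.439 CPM while LOC_Os10g41400.1 rose from 156 ± 12.7 to 256 ± 29.2 CPM. For ATRAN3, a small GTPase of nuclear transport, LOC_Os05g49890.1 fell from 243 ± 18.3 to 61.7 ± 20.003 CPM and LOC_Os05g49890.2 rose from 7.61 ± 7.88 to 207 ± 38.0 CPM. How reads shared by isoforms were assigned is not given in the sources used here. The biological coefficient of variation was higher for isoforms than for genes, 46.6% against 24.5%. Without wild-type replicate 1, 3183 transcripts passed. Without mutant replicate 3 no transcript passed (smallest adjusted p = 0.0506, with 8283 transcripts at an unadjusted p under 0.05), and the count was 541 without wild-type replicate 3, 1022 without wild-type replicate 2 and 1115 without mutant replicate 2.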

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

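The scaling with library totals only, the refit without photosynthesis genes and the removal of regions were chosen after the data were examined. Depth was 32564678 to 40618376 counts per library, and its effect was not tested. The gene count stayed within 1.5 times of 7695 under DESeq2 (9907), limma-voom (7878), median-of-ratios factors (7694), no filter (7284), the stricter filter (5386), log2(TPM + 1) (8417), library totals (8331) and without the 2285 genes near loci detected in 1 genotype only (6870). Of the main calls, 7682 were shared with DESeq2 and 7439 with limma-voom, with 0 in the opposite direction under any setting. A fold minimum of 2 left 4547 genes (1932 higher). Leaving out 1 library gave 3747 to 7746 genes, 1626 to 3938 of them higher and 2119 to 3808 lower, with fewer samples in each fit. Library totals gave 5142 higher and 3189 lower genes and a median over all genes of 0.13, and log2(TPM + 1) a median of 0.11, against 0.00 with TMM. With library totals the auxin and sucrose list medians read 0.01 and 0.06 rather than -0.12 and -0.07. For transcripts the higher share moved from 45.9% to 56.8% and 57.5% under these settings.

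Transcript calls were the least stable: 9640 under DESeq2 (4617 higher, 5023 lower), 3482 higher under log2(TPM + 1), 1283 higher at 2-fold or more, and 0 to 3183 with 1 library left out (0 to 1360 higher, 0 to 1823 lower). The causes were not tested. Fits of the same size gave 3183 transcripts without wild-type replicate 1, 1022 without wild-type replicate 2 and 541 without wild-type replicate 3. The number of samples alone therefore does not set the count.

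Whether the shared numbers 2 and 3 pair the libraries is not known, since the labels give them no meaning. Only 2 pairs exist, whose deviations correlated at 0.038 across genes, which is too few to decide it. With a replicate block on these 4 libraries 5766 genes were called, 5122 of them among the main calls, and 0 transcripts (8365 at an unadjusted p under 0.05), 0 higher and 0 lower; without the block the same 4 libraries gave 7746 and 3183. The block called 10 lists.

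Camera called 8 lists, 0 with an estimated correlation, 14 in fry, 7 in the refit without photosynthesis genes, which leaves 1 list out, and 5 to 10 with 1 library left out. The difference in storage protein CPM, 0.104, ranged from -0.559 to 0.767 with 1 library left out, within the spread between libraries.

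Of 148 named genes past the threshold, 125 to 145 kept their call with 1 library left out and 140 under the block, and none changed direction. Some gene values changed sign and some list tests changed direction. None of them was past the threshold with all libraries or in the setting named, and the cause was not tested. With 1 library left out, the log2 fold change of LOC_Os10g26060 ranged from -0.0509 to 0.580, of LOC_Os03g07250 from -0.0763 to 1.01, of LOC_Os09g27620 from -0.357 to 0.537 and of LOC_Os09g32930 from -0.146 to 0.354. Under the block LOC_Os09g27620 read -0.388 and LOC_Os09g32930 -0.00879. Some lists changed the direction of their test with 1 library left out. Their medians ranged from -0.352 to -0.0336 for starch synthesis (direction changed without mutant replicate 3) and -0.729 to 0.0102 for LEA proteins. The ranges were -0.228 to 0.114 for small heat shock proteins and 0.0506 to 0.630 for pathogenesis-related proteins. They were -0.209 to 0.0585 for transposons (-0.0182 under the block) and -0.0574 to 0.0784 for the respiratory chain. In other lists the median changed sign but the test did not. Without mutant replicate 2 it was 0.0430 for sucrose and -0.0589 for larger heat shock genes. Without mutant replicate 3 it was -0.00268 for antioxidant enzymes and -0.00809 for NB-ARC genes. The test also changed direction under the stricter filter for gibberellin (median -0.232), cytokinin (-0.0167) and NB-ARC genes (-0.0657), and in fry for gibberellin (-0.282), cytokinin (0.0516) and the respiratory chain (0.0132).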

Other observations

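The tests on clustering, stages, scaling, the photosynthesis share and cyclins, and all lists of floral genes and KEGG pathways, were chosen after the results were seen. The libraries held transcripts of floral organ identity genes, MADS-box factors named after Arabidopsis relatives. All 3 genes of the stamen and lodicule list were lower in the mutant in edgeR: AP3 (LOC_Os06g49840) fell from 628 ± 12.6 to 149 ± 33.5 CPM, PI (LOC_Os01g66030) from 261 ± 17.8 to 63.6 ± 12.3 CPM and PI at LOC_Os05g34940 from 36.9 ± 1.71 to 21.1 ± 2.29 CPM. Genes named AG, of carpels and stamens, went both ways, 2 higher and 2 lower of 5 (3 and 2 adjusted over the list alone). Of these, LOC_Os05g11380 lost its call with any 1 library left out (adjusted p in edgeR 0.0530 to 0.147) and with library totals (0.0504), and LOC_Os12g10540 without wild-type replicate 3 (0.0713), mutant replicate 2 (0.0701) or mutant replicate 3 (0.0539). LOC_Os01g66290 rose from 15.5 ± 4.09 to 76.3 ± 14.5 CPM and LOC_Os01g10504 fell from 115 ± 3.17 to 60.1 ± 15.2 CPM. Of 11 SEP, AGL6 and AP1 type genes, 1 passed and 0 adjusted over the list alone. This was AGL9 at LOC_Os09g32948, and its call was lost without wild-type replicate 1 (adjusted p = 0.0585 in edgeR), wild-type replicate 2 (0.109), wild-type replicate 3 (0.124) or mutant replicate 2 (0.176). AGL2 (LOC_Os03g11614) had 820 ± 117 and 1073 ± 122 CPM. Of 17 anther and tapetum genes, 9 fell and 1 rose, also adjusted over the list alone, with a median of -1.38 (camera adjusted p = 0.0125 over 4 lists; adjusted p = 0.379 with an estimated correlation). LOC_Os11g37280 fell from 20.8 ± 7.93 to 0.105 ± 0.0755 CPM, AMS (LOC_Os02g02820), a regulator of tapetum, from 24.9 ± 4.80 to 1.97 ± 1.63 CPM, and LOC_Os03g08790, an aspartyl protease, rose from 8.30 ± 2.42 to 75.0 ± 13.4 CPM. Of 6 meiosis genes, 2 fell and none rose (2 and 2 adjusted over the list alone), and the list's median was 0.43.

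Among 124 KEGG pathways, camera called 32 higher and 7 lower, 0 of them with an estimated correlation (10 had an unadjusted p under 0.05, the lowest 0.0194 for tyrosine metabolism), and fry called 66. Of 305 Ribosome genes, 181 rose and 10 fell (median 0.62, camera adjusted p = 7.7e-13; adjusted p = 0.594 with an estimated correlation). Of 45 DNA replication genes, 28 rose and none fell (median 0.70; adjusted p = 0.541 with an estimated correlation), and of 36 mismatch repair genes 16 rose and none fell. In the pathway of xenobiotic metabolism, largely glutathione transferases in plants, 20 of 50 rose and 1 fell. Of 205 genes of plant hormone signal transduction, 56 fell and 21 rose, of 64 genes of plant MAPK signalling 22 fell and 6 rose, and of 25 ether lipid genes 13 fell and 1 rose.

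The first pattern is the set of 27 genes detected in the mutant libraries only. Of these, 21 had another member within 500 kb, against a median of 2 and a highest value of 12 in 10000 random sets (permutation test, p = 1e-04, the smallest they can give). The random sets were not matched for families of neighbouring genes, such as the wall-associated kinases here. The test was also chosen after runs of neighbours were seen. Segments that differ between the lines may contribute, but the clustering alone does not single them out. Among the 26 genes detected in the wild type only, 2 had a neighbour (permutation test, p = 0.645). This leaves such segments open for them, since a segment of a single gene gives no neighbour. Of the 16 described genes, 3 had a lower gene of the same description nearby. Copies described otherwise, lying elsewhere or falling too little to be called were not counted. The count therefore cannot decide whether reads shifted between copies. Other genes of the regions were called at 2-fold or more in 27.0% of cases against 17.1% elsewhere. Of those 182, 67.0% were higher (95% Wilson interval 59.9% to 73.4%) against 41.1% elsewhere, as release of silenced regions in the mutant would give. The regions were picked by genes higher in the mutant, so neighbouring copies can raise this share. The interval treats neighbours as independent. Differing segments, released silencing and shifted reads all stay open as hypotheses. The 12 tested transposon genes, with a median of 0.03 and 0 calls in edgeR, do not decide among them.

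The second pattern is lower stamen and anther transcripts. Another scaling moved no member by more than 0.14 on the log2 scale, which argues against scaling. If the mutant material held less stamen RNA, other genes described as of pollen, anther or stamen could be lower too: the 21 tested had a median of -0.14, within random lists (-0.32 to 0.31), with 7 lower and 3 higher. The most abundant, SAH7 (LOC_Os04g32680), fell from 1268 ± 71.5 to 303 ± 22.8 CPM, but most belong to the Ole e 1 family, which other tissues express too. Outside that family, MSP2 (LOC_Os06g03630), described as microspore-specific, fell from 10.6 ± 2.69 to 0.285 ± 0.0679 CPM. NPGR2, named for pollen germination, fell at LOC_Os03g04500 (log2 fold change -0.69) and did not pass at LOC_Os10g33290 (-0.14). NPGR1 (0.63) and ATVT-1, described as of vascular tissue and tapetum (-0.19), did not pass. These genes were chosen later. The median therefore cannot decide whether the mutant material held less stamen RNA. A difference in stage cannot be told apart from less stamen RNA. The meiosis median lay 1.81 above the anther median, but only 6 meiosis genes were tested, and the labels give a single stage.

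The third pattern is higher ribosome and DNA replication genes with lower photosynthesis genes. Removing the trend with gene length left the Ribosome median at 0.60, above random lists of matched expression (upper bound 0.04), and the DNA replication, proteasome and histone medians also stayed above theirs, which argues against length. Photosynthesis genes, including those of KEGG, held at most 5.17% of a wild-type library and at least 3.42% of a mutant one, which can raise all other genes by at most 0.0263 on the log2 scale, far under the Ribosome median of 0.62. A larger share of dividing tissue may explain it and stays open. In the KEGG cell cycle pathway, 34 of 112 genes rose and 6 fell, with a median of 0.35. Its adjusted p was 0.000526 in camera and 0.594 in camera with an estimated correlation. The cyclin-dependent kinase list had a median of 0.28, within random lists (upper bound 0.41). That list also holds inhibitors of these kinases and no cyclin, so it decides little. A direct effect of the mutation was not tested.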
